A study of Mus musculus with 6 samples.

How the data were processed

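Hearts of 18-month-old wild-type female mice were sampled after sham or TAC surgery, 3 per group, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was enriched on oligo(dT) beads, and libraries were made with the NEBNext Ultra kit and sequenced on an Illumina NovaSeq. The protocol does not state that the kit kept the strand, so reads of overlapping genes on opposite strands may not have been told apart. The deposited table lists 22298 mouse genes by Ensembl identifier, with an estimated count and an FPKM value, scaled by gene length and depth, for each library, per the file headers. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2 were used on GRCm38. Which tool made which column, the annotation release and any filter are not given in the sources used here. Of the genes with a count above 0 in a library, 88.7% to 89.7% had an exactly whole estimated count (no tolerance), and a fractional value shows that reads were divided between genes. The deposited FPKM values per estimated count, over 7835 genes with at least 200 counts in every library, scaled inversely with a library's total estimated count (the product ranged from 22.98 to 22.99 in relative units). FPKM was thus scaled by that total and not by a normalization robust to a few abundant genes.

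Gene symbols and coordinates came from a GRCm38 annotation, the same build, which matched 22255 of the 22298 identifiers. The other 43 held at most 0.00196% of the counts of a library. Of the genes, 21783 were protein coding, so long noncoding RNAs were mostly not analysed here. In 4833 genes the count was 0 in all libraries. The list of sex-specific genes was used only to check labels: its 4 genes of the Y chromosome held 6 counts in all over the 6 libraries, and none of the list was tested. Depth ranged from 19747265 to 27549838 estimated counts per library. All sham pairs and all TAC pairs differed by far more than sampling noise (chi-square per degree of freedom of 11.6 to 17.8 between sham libraries and 75.8 to 100 between TAC libraries), so each was kept as its own sample.

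Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM normalization, glmQLFit and glmQLFTest), TAC against sham, two-sided, with Benjamini-Hochberg adjustment over the 13708 genes left and a threshold of 0.05. No covariate was used. CPM are on the TMM-scaled library sizes. The standard error printed beside a log2 fold change is its size divided by the square root of the F statistic, an approximation. Common dispersion was 0.0473, a biological coefficient of variation of 21.7%. The median log2 fold change of all tested genes was 0.03. For Trex1 and Gper1 the exact two-sided permutation test was run on log2 of CPM plus 0.5.

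Before the data were examined, 29 gene lists were fixed, of cell types, heart genes, metabolism, stress and immunity. The 28 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 28 lists. At the preset correlation 18 lists were called, and with a correlation estimated for each list 0 were. Each camera call thus depends on the assumption that the members of the list vary nearly independently between animals. The same lists were tested with fry, which does not use the preset correlation and called 4. A count adjusted over the list alone uses only the p-values of its members. The rule for named genes was also fixed before the data were examined. Its first part took the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 1 CPM, no overlap between groups and a proper symbol. Its second part was 12 fixed genes (Trex1, Gper1, Nppa, Nppb, Myh7, Myh6, Atp2a2, Col1a1, Col3a1, Postn, S100a8 and S100a9). Its last part took, per list, up to 4 called members with the smallest adjusted p or, with none called, the 2 most abundant. Other genes are named where 5 or fewer passed, where a later observation concerns them or where they limit what a list covers. These were chosen after their values were seen. A result for 1 gene that the rule names is not reported here.

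Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile factors, the Wald test of DESeq2 1.42.0, and limma-voom with and without library weights. Also planned were no filter on low counts, a minimum count of 100, thresholds with a log2 fold change of 1 or an adjusted p under 0.10, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma-trend on log2 CPM, limma-trend on log2 of FPKM plus 1 (genes with FPKM of at least 1 in at least 3 libraries), the test without the 13 mitochondrially encoded genes, and the test without genes that have fractional counts. The planned changes of pseudocount applied to normalized values and were not needed for counts. Simulated counts with the means, dispersions and library sizes of this comparison and 200 changed genes were tested over 13567 genes. In them edgeR recovered 43% of the 2-fold and 88% of the 4-fold changes with 2.96% false calls, and DESeq2 recovered 62% and 92% with 21.8% false calls. A simulated shift of 0.5 in 1 of 28 lists was called (camera adjusted p = 2.02e-19) with 0 other lists called. Each simulated gene was drawn independently, whereas the estimated correlation reached 0.922 in the real respiratory chain list. The simulation thus does not cover false list calls from members that vary together. The share of false gene calls depends on how many genes change, so the simulated shares need not hold in the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for permutations and plots.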

Results

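Poly(A)-selected RNA from hearts of 18-month-old wild-type female mice was sequenced in 6 libraries, 3 after sham surgery and 3 after TAC surgery. TAC is the usual abbreviation, in work on the heart, for transverse aortic constriction, a narrowing of the aorta that loads the left ventricle with pressure. The time between surgery and sampling is not given in the sources used here. The series title concerns GPR30, the membrane estrogen receptor encoded by Gper1, the exonuclease gene Trex1, and the breakdown of neutrophil extracellular traps (NETs), the DNA webs that neutrophils release, in heart failure of aged females. The question taken from it was which genes differed between TAC and sham hearts, and whether Trex1, Gper1 and neutrophil genes were among them. Total estimated counts were 19747265, 27549838 and 21091881 in sham replicates 1, 2 and 3. They were 25799573, 23361356 and 22172718 in TAC replicates 1, 2 and 3. The 13 mitochondrially encoded genes took between 25.7% and 30.5% of the counts of a library. The labels describe 3 heart samples per group and do not state that each came from a different animal, so the p-values measure the spread between these samples.

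TAC hearts had higher RNA for natriuretic peptide B and the slow myosin heavy chain, for some neutrophil, macrophage and chemokine genes, and for some chaperones of the endoplasmic reticulum. Gene lists of the respiratory chain and of fatty acid oxidation were called lower at the preset correlation, although no single member passed the test. Neither list was called with an estimated correlation (adjusted p = 0.515 and 0.511) or with fry (adjusted p = 0.256 and 0.218). Of 13708 genes tested, 153 were higher and 74 lower in TAC at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 124 of the higher and 49 of the lower genes changed at least 2-fold, a log2 change of 1. All 227 had no overlap between the 3 sham and the 3 TAC values, as had 31.5% of all tested genes, where chance gives 10%. The first principal component held 54.6% of the variance of log2 CPM, counts scaled to a common library size, and placed the sham libraries between -37.3 and -31.4. It placed TAC replicate 1 at 0.65, TAC replicate 2 at 48.9 and TAC replicate 3 at 53.5. The log2 CPM of TAC replicate 1 correlated with those of the sham libraries at 0.971 to 0.975 and with TAC replicates 2 and 3 at 0.961 and 0.957. The counts changed widely when 1 library was left out, in fits that also have fewer samples. Without TAC replicate 1, 1837 genes were higher and 1392 lower. Without TAC replicate 2 the counts were 20 and 16, and without TAC replicate 3 they were 82 and 52. Without sham replicates 1, 2 and 3 they were 6 and 10, 7 and 9, and 4 and 8. None of the 227 genes changed sign in any of these fits, which their lack of overlap between the groups made nearly certain beforehand. Of the 46 called genes that are named here by rule, 7 stayed past the threshold without any given sham library, 46 without TAC replicate 1, 10 without TAC replicate 2 and 26 without TAC replicate 3. DESeq2's Wald test called 1071 higher and 598 lower genes, among them all 227.

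**Figure D1:**
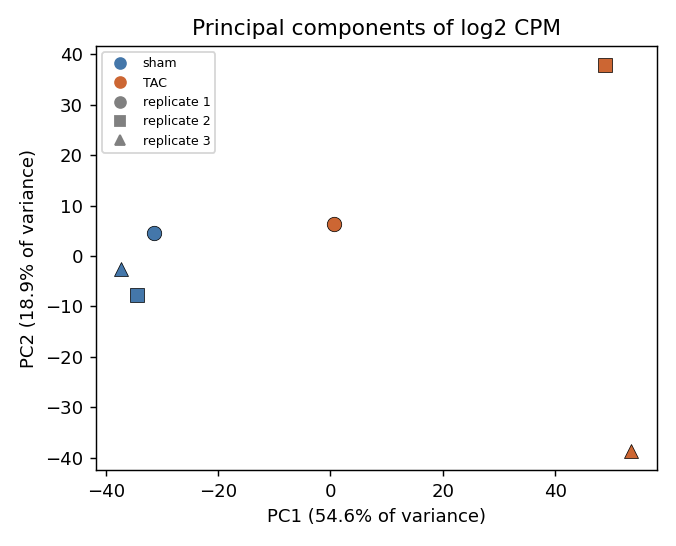
First and second principal components of log2 CPM over the 13708 tested genes, 1 point per library, with colours for sham and TAC and marker shapes for the replicate number. TAC replicate 1 sits at 0.65 on the first component, between the sham libraries and TAC replicates 2 and 3 at 48.9 and 53.5.

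Some genes of the fetal heart program and of the response to stretch were higher in TAC. Nppb, which encodes natriuretic peptide B (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205 in GRCm38), was 12.4-fold higher in TAC. It stood at 42.4 ± 5.26 CPM in sham and 524 ± 339 CPM in TAC (SD, n = 3 each), a log2 fold change of 3.63 (SE 0.52, edgeR adjusted p = 0.0242). Its values in TAC replicates 1, 2 and 3 were 167, 564 and 842 CPM. Myh7, the slow myosin heavy chain, rose by a log2 fold change of 4.03 (SE 0.70, edgeR adjusted p = 0.0379). Its deposited counts were fractional, so some of its reads were divided between genes. Ankrd1, a sarcomeric stress-response gene, rose by 2.85 (SE 0.37, edgeR adjusted p = 0.0172). Of 19 tested members, these 3 were higher, none was lower and 16 did not pass. Adjusted over the list alone 13 were higher and 1, the apoptosis gene Hrk, was lower. The list as a whole was shifted up (median log2 fold change 0.77, camera adjusted p = 1.28e-04), with an adjusted p = 0.430 with an estimated correlation. Nppa, which encodes natriuretic peptide A and is abundant in the atria, did not pass. It was at 1621 ± 410 CPM in sham and 2114 ± 306 CPM in TAC (log2 fold change 0.38, SE 0.21, adjusted p = 0.283). The median of the list in TAC replicates 1, 2 and 3 was 0.22, 0.85 and 1.45 log2 units above the sham mean.

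Neutrophil and NET genes had the largest shift of the 28 lists tested. S100a8 and S100a9, the subunits of calprotectin and among the most abundant transcripts of neutrophils, rose by log2 fold changes of 4.97 (SE 0.84, edgeR adjusted p = 0.0363) and 4.77 (SE 0.77, adjusted p = 0.0327). S100a9 went from 1.33 ± 1.02 CPM in sham to 35.2 ± 23.02 CPM in TAC (SD, n = 3 each). TAC replicates 1, 2 and 3 had 8.75, 46.4 and 50.5 CPM. Lcn2, an iron-binding protein of neutrophil granules that other stressed cells also make, rose by 4.18 (SE 0.48, adjusted p = 0.0122). Ncf1, a subunit of the phagocyte NADPH oxidase, rose by 1.18 (SE 0.19, adjusted p = 0.0320). With the granule collagenase Mmp8, 5 of 18 tested members were higher, 0 lower and 13 did not pass. Adjusted over the list alone 17 were higher. The exception was Padi4, which encodes an enzyme of NET formation (log2 fold change 0.94, SE 0.47, edgeR adjusted p = 0.247). The list holds 28 genes, and the untested ones, among them Mpo, Elane, Prtn3 and Ctsg, had too few counts. The median log2 fold change was 3.19 (camera adjusted p = 1.03e-10), with an adjusted p = 0.386 with an estimated correlation. Some marker genes of red blood cells and platelets were also higher in TAC. Their list did not follow the neutrophil list from library to library. In the red cell and platelet list 3 of 11 members were higher and 8 did not pass (all 11 higher adjusted over the list alone). Slc4a1, the anion exchanger of red cells, rose by 3.38 (SE 0.56, adjusted p = 0.0336). Itga2b, a platelet integrin, rose by 1.58 (SE 0.27, adjusted p = 0.0371), and Alas2, of haem synthesis in red cell precursors, by 1.36 (SE 0.24, adjusted p = 0.0397). The counts of Alas2 were fractional. The red cell and platelet list was shifted up with a median of 1.35 (camera adjusted p = 3.20e-07), and its adjusted p = 0.386 with an estimated correlation and 0.0484 with fry. Its medians in TAC replicates 1, 2 and 3 were 1.58, 0.78 and 1.28 above the sham mean, and those of the neutrophil list 1.37, 2.95 and 3.26.

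Some chemokine, cytokine and adhesion genes were also higher in TAC. Ccl8, a chemokine that draws monocytes, went from 0.877 ± 0.25 CPM in sham to 28.7 ± 25.7 CPM in TAC (SD, n = 3 each), a log2 fold change of 5.05 (SE 0.69, edgeR adjusted p = 0.0227). Vcam1, the endothelial adhesion molecule for leukocytes, doubled within a narrow spread, from 41.9 ± 3.08 to 83.9 ± 1.69 CPM (log2 fold change 1.00, SE 0.11, adjusted p = 0.00837). Ccl11, which attracts eosinophils, rose by 1.99 (SE 0.28, adjusted p = 0.0229), and Il33, an alarmin cytokine, by 1.20 (SE 0.17, adjusted p = 0.0237). Of 24 tested members 7 were higher, 0 lower and 17 did not pass, and 20 were higher adjusted over the list alone. The list was shifted up (median 2.01, camera adjusted p = 2.07e-10, adjusted p = 0.386 with an estimated correlation and 0.0484 with fry). Among macrophage markers, Ccr2, the receptor of recruited monocytes, rose by 2.86 (SE 0.46, adjusted p = 0.0327) and Cd68 by 1.56 (SE 0.26, adjusted p = 0.0359). Plac8 rose by 1.85 (SE 0.33, adjusted p = 0.0391) and the mannose receptor gene Mrc1 by 1.39 (SE 0.26, adjusted p = 0.0436). These were the 4 higher genes of 22, with 0 lower and 18 not passing, and 17 were higher adjusted over the list alone. The macrophage list was shifted up (median 0.91, camera adjusted p = 3.71e-09, adjusted p = 0.386 with an estimated correlation).

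**Figure D2:**
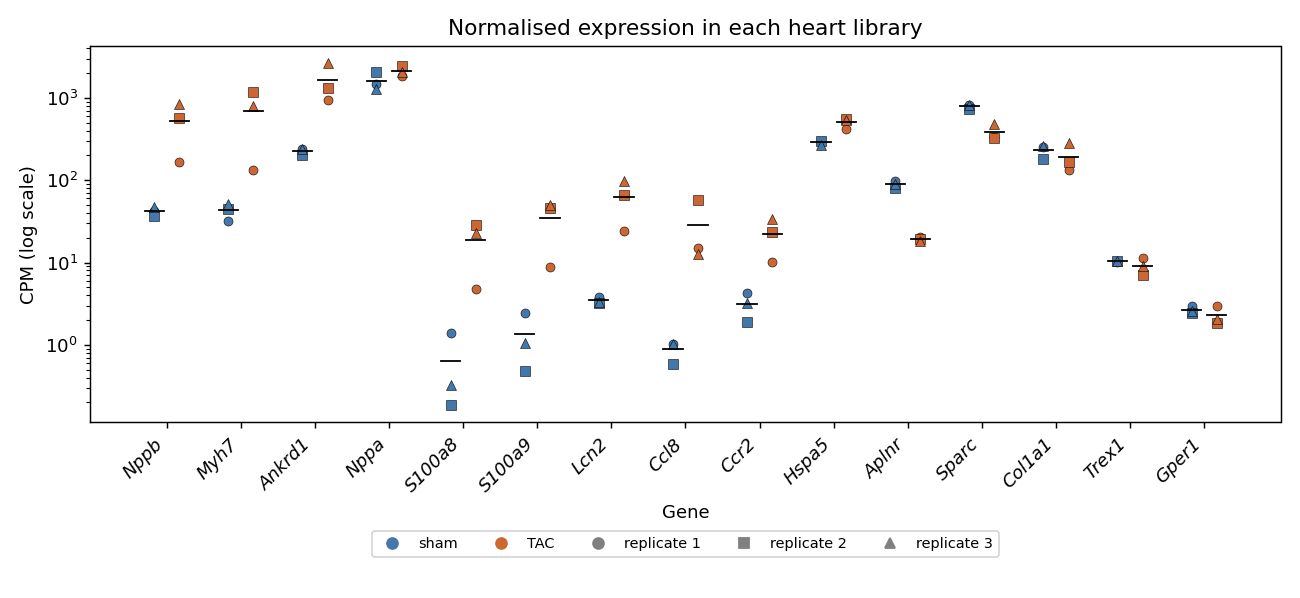
CPM on a log scale for 15 genes in each of the 6 libraries, with colours for sham and TAC, marker shapes for the replicate number and a black bar at each group mean. Nppb, Myh7, Ankrd1, S100a8, S100a9, Lcn2, Ccl8, Ccr2 and Hspa5 are above all sham values in all 3 TAC libraries, Aplnr and Sparc are below them, and Nppa, Col1a1, Trex1 and Gper1 overlap.

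Trex1 and Gper1, the genes of the series title, did not differ detectably between the groups. Trex1 (ENSMUSG00000049734, chromosome 9, 109057933 to 109059734 on the minus strand in GRCm38, overlapping Atrip) stood at 10.4 ± 0.305 CPM in sham and 9.18 ± 2.18 CPM in TAC (SD, n = 3 each). TAC replicates 1, 2 and 3 had 11.4, 7.03 and 9.10 CPM. Its log2 fold change was -0.17 (SE 0.19, edgeR adjusted p = 0.591 over all genes and 0.446 adjusted over the list alone of these 2 genes). The exact two-sided permutation test gave p = 0.4 for Trex1, where the smallest p that 3 against 3 allows is 0.1. Its estimated counts were fractional, so some of its reads were divided between genes, and the overlap with Atrip adds to this uncertainty. Gper1 (ENSMUSG00000053647, chromosome 5, 139423151 to 139427800) was at 2.66 ± 0.276 CPM in sham and 2.28 ± 0.610 CPM in TAC. TAC replicates 1, 2 and 3 had 2.97, 1.82 and 2.04 CPM of it. Its log2 fold change was -0.22 (SE 0.27, edgeR adjusted p = 0.636 over all genes and 0.446 adjusted over the list alone), and the exact two-sided permutation test gave p = 0.3. The gene 3110082I17Rik overlaps Gper1. Among 14 tested members of a list of DNA-degrading nucleases and related enzymes, none passed. Dnase1, at a mean of 0.93 CPM in sham and 0.20 CPM in TAC, was too low to be tested. Adjusted over the list alone 1 was higher, the endolysosomal exonuclease gene Pld4 (log2 fold change 0.89, SE 0.19, adjusted p = 0.0602 over all genes). The 2 most abundant, Samhd1 and Pld3, had log2 fold changes of 0.31 (SE 0.11) and 0.20 (SE 0.12). The list was not shifted (median 0.18, camera adjusted p = 0.319, adjusted p = 0.511 with an estimated correlation).

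Sensors of cytosolic DNA were shifted up as a list, with 1 of 16 members higher, 0 lower and 15 not passing and 6 higher adjusted over the list alone (median 0.37, camera adjusted p = 0.00250, adjusted p = 0.386 with an estimated correlation and 0.0484 with fry). The member that rose was Ifi204, an interferon-inducible DNA sensor of a multigene family (log2 fold change 1.41, SE 0.20, edgeR adjusted p = 0.0242), whose counts were fractional and so are uncertain between its near-identical copies. Of 30 interferon response genes, only Oas3, which makes the activator of an antiviral nuclease, was higher (1.76, SE 0.33, adjusted p = 0.0471), and it was also the only one adjusted over the list alone. That list was not shifted (median 0.09, camera adjusted p = 0.388), although without TAC replicate 3 it was called higher (adjusted p = 0.0133). Its direction was down, not called, without sham replicate 2 (adjusted p = 0.893) and without TAC replicate 1 (adjusted p = 0.287). None of 11 estrogen receptor and estrogen-response genes passed over all genes or adjusted over the list alone. The abundant members Ncor1, a nuclear corepressor, and Esrra, an orphan receptor of energy metabolism, had log2 fold changes of 0.35 (SE 0.16) and -0.21 (SE 0.11). The estrogen list had a median of -0.14 (camera adjusted p = 0.126), and of the 6 fits without 1 library only that without TAC replicate 2 called it lower (adjusted p = 0.0433).

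Collagen genes of fibrosis were not higher in TAC. Col1a1 was at 230 ± 42.4 CPM in sham and 193 ± 77.4 CPM in TAC (SD, n = 3 each; log2 fold change -0.25, SE 0.28, edgeR adjusted p = 0.592). Col3a1 was at 593 ± 113 and 510 ± 276 CPM (log2 fold change -0.22, SE 0.34, adjusted p = 0.715). Postn, a matrix protein of activated fibroblasts, had a log2 fold change of 0.74 (SE 0.23) that did not pass (adjusted p = 0.0983). Sparc, a collagen-binding matrix protein, was the only one of 36 fibrosis and matrix genes to pass. It fell from 789 ± 52.2 to 383 ± 88.8 CPM (log2 fold change -1.04, SE 0.18, adjusted p = 0.0391). Adjusted over the list alone, 7 of the 36 were higher and 5 lower. The list was not shifted (median 0.01, mean 0.25, camera direction down with adjusted p = 0.469), and without TAC replicate 3 it was called lower (adjusted p = 0.00566). Without TAC replicate 1 its direction was up, not called (adjusted p = 0.203). Its medians in TAC replicates 1, 2 and 3 were -0.55, -0.02 and 0.49.

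Few marker genes of resident vascular and stromal cells passed over all genes. Of 22 endothelial markers, Aqp1, the water channel, fell by 1.02 on the log2 scale (SE 0.17, edgeR adjusted p = 0.0363) and Tie1, a receptor of the angiopoietin pathway, by 0.63 (SE 0.11, adjusted p = 0.0414), with 0 higher and 20 not passing. Adjusted over the list alone, 4 endothelial markers were higher and 3 lower. The list was not shifted (median -0.10, mean 0.02, camera direction down with adjusted p = 0.344). None of 17 smooth muscle and pericyte markers passed over all genes and 6 were lower adjusted over the list alone. The list was shifted down (median -0.29, camera adjusted p = 0.00208, adjusted p = 0.386 with an estimated correlation). Its most abundant members, the desmin gene Des and the pericyte gene Rgs5, had log2 fold changes of 0.44 (SE 0.23) and 0.14 (SE 0.21). None of 20 markers of resting fibroblasts passed, and adjusted over the list alone 1 was higher and 4 were lower. That list was also shifted down (median -0.28, camera adjusted p = 0.00269, adjusted p = 0.386 with an estimated correlation). Gsn, which encodes gelsolin, was at a log2 fold change of -1.12 (SE 0.29, adjusted p = 0.0733) and the proteoglycan gene Dcn at -0.19 (SE 0.23, adjusted p = 0.623).

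Gene lists of oxidative metabolism were called lower in TAC at the preset correlation only, by small amounts per gene. All 36 tested nuclear genes of the respiratory chain had a negative log2 fold change (median -0.28, camera adjusted p = 3.05e-07, adjusted p = 0.515 with an estimated correlation). None passed over all genes or adjusted over the list alone. The ATP synthase genes Atp5b and Atp5a1, the most abundant of them, were at -0.31 (SE 0.18, edgeR adjusted p = 0.304) and -0.35 (SE 0.18, adjusted p = 0.254). Of 32 fatty acid oxidation genes, 3 had a positive log2 fold change and 0 passed over all genes or adjusted over the list alone (median -0.38, camera adjusted p = 1.22e-06, adjusted p = 0.511 with an estimated correlation). Its most abundant members, the fatty acid binding protein gene Fabp3 and the lipase gene Lpl, had log2 fold changes of -0.19 (SE 0.22) and 0.15 (SE 0.27). In both lists TAC replicate 1 sat at the sham level, with medians of 0.03 and -0.03, against -0.38 and -0.55 in TAC replicate 2 and -0.54 and -0.68 in TAC replicate 3. The 13 genes encoded by the mitochondrial genome were shifted the other way (median 0.42, camera adjusted p = 0.0144, adjusted p = 0.551 with an estimated correlation). This call was lost without sham replicate 3 (adjusted p = 0.0711) or TAC replicate 1 (adjusted p = 0.0793) and without the filter on low counts (adjusted p = 0.0747). None of the 13 passed over all genes, and adjusted over the list alone mt-Atp8, mt-Nd4 and mt-Nd4l were higher. The abundant mt-Co1 and mt-Co3 had log2 fold changes of -0.15 (SE 0.17) and -0.01 (SE 0.17). None of 24 glycolysis genes passed over all genes or adjusted over the list alone (median -0.04, mean 0.08, camera direction down with adjusted p = 0.607). Gapdh was at 0.08 (SE 0.13) and Pkm at 0.01 (SE 0.14).

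Adult contractile and calcium handling genes were slightly lower as a list, with 0 of 24 passing. Myh6, the fast myosin heavy chain of the adult mouse heart, was at 19590 ± 609 CPM in sham and 14112 ± 2512 CPM in TAC (SD, n = 3 each; log2 fold change -0.47, SE 0.17, edgeR adjusted p = 0.138). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at -0.50 (SE 0.22, adjusted p = 0.2). Adjusted over the list alone 1 member was higher and 1 lower, from the pair of Kcnj2 and Slc8a1. The list median was -0.19 (camera adjusted p = 0.0272, adjusted p = 0.538 with an estimated correlation). The call was lost without sham replicate 1 (adjusted p = 0.0507) or TAC replicate 3 (adjusted p = 0.245).

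Of 29 chaperone and unfolded protein response genes, 6 were higher in TAC. Manf, a protein secreted under stress of the endoplasmic reticulum, rose from 22.5 ± 1.26 to 56.0 ± 16.9 CPM (SD, n = 3 each; log2 fold change 1.32, SE 0.22, edgeR adjusted p = 0.0336). Hsp90aa1, the inducible cytosolic chaperone, rose by 1.86 (SE 0.34, adjusted p = 0.0419). Hspb7, a small heat shock protein of heart muscle, rose by 0.98 (SE 0.18, adjusted p = 0.0414), and Dnaja1, an HSP70 cochaperone with fractional counts, by 0.88 (SE 0.14, adjusted p = 0.0320). With Sdf2l1 and Hspa5, the latter the main chaperone of the endoplasmic reticulum, 6 of 29 were higher, 0 lower and 23 did not pass, and 17 were higher adjusted over the list alone. The list was shifted up (median 0.82, camera adjusted p = 1.03e-06, adjusted p = 0.386 with an estimated correlation). All 24 tested immediate early genes had a positive log2 fold change, and none passed over all genes, while 6 were higher adjusted over the list alone. That list was shifted up (median 0.88, camera adjusted p = 3.06e-05, adjusted p = 0.511 with an estimated correlation). The transcription factor gene Klf6 came nearest (log2 fold change 0.72, SE 0.14, adjusted p = 0.05003), and Dusp1, the most abundant with it, was at 0.06 (SE 0.25). The immediate early median was 0.01 in TAC replicate 1, 1.07 in TAC replicate 2 and 1.26 in TAC replicate 3. None of 28 cell cycle genes passed over all genes or adjusted over the list alone (median 0.12, camera adjusted p = 0.956). Pcna was at 0.18 (SE 0.14) and Mcm6 at 0.50 (SE 0.24).

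**Figure D3:**
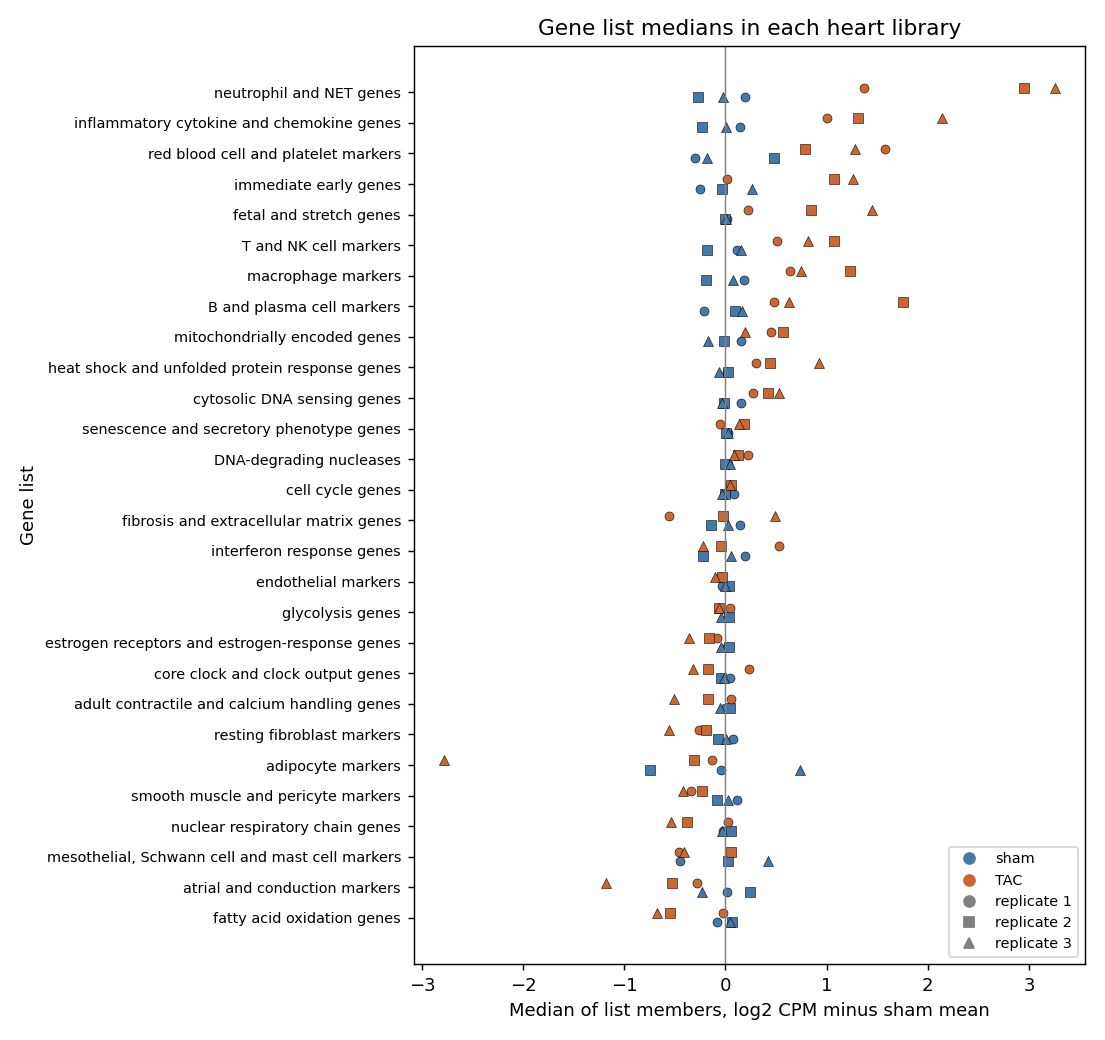
Median over the members of each of 28 gene lists of log2 CPM minus the sham mean, 1 point per library, with colours for sham and TAC and marker shapes for the replicate number. The neutrophil and NET list reached 1.37, 2.95 and 3.26 in TAC replicates 1, 2 and 3, and the fatty acid oxidation list -0.03, -0.55 and -0.68.

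The largest changes named by rule included genes with nearly no reads in one group. Tpm3-rs7, a gene related to the tropomyosin gene Tpm3, rose from 0.194 ± 0.0429 CPM in sham to 78.7 ± 24.4 CPM in TAC (SD, n = 3 each; log2 fold change 8.65, SE 0.35, edgeR adjusted p = 3.71e-05). Its counts were fractional and so uncertain. Most of the other largest increases were myeloid or chemokine genes. Cd177, a neutrophil surface protein, went from 0.0154 ± 0.0267 to 2.78 ± 2.23 CPM. The macrophage chitinase-like gene Chil3, the neutrophil chemokine Cxcl5 and the innate immune receptor Clec4e had log2 fold changes of 6.20 (SE 1.13), 4.89 (SE 0.93) and 4.85 (SE 0.81). Pttg1, which encodes securin of the cell cycle, had the largest decrease named by the rule. It fell from 62.3 ± 2.68 to 3.62 ± 0.183 CPM (log2 fold change -4.10, SE 0.13, adjusted p = 8.25e-06), and the TAC libraries had 3.83, 3.47 and 3.57 CPM. Other genes that fell were Agpat4, an acyltransferase (-3.77, SE 0.24), Cyfip2, of the actin-regulating WAVE complex (-3.56, SE 0.22), Ndrg4 (-2.90, SE 0.22) and Aplnr, the receptor of apelin (-2.22, SE 0.12). Olfr1396, Col28a1, the potassium channel subunit gene Kcne1, Cilp2 and the basement membrane collagen gene Col4a3 completed the 10, with log2 fold changes between -3.45 and -1.99. Pttg1, Cyfip2 and Olfr1396 all lie on chromosome 11, at starts of 43420250, 46193850 and 49109982 in GRCm38.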

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

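The tests on FPKM, on log2 CPM, without mitochondrial genes and without genes with fractional counts were chosen after seeing the data. The main counts were 153 higher and 74 lower genes. They were 1131 and 479 at an adjusted p under 0.10, 1071 and 598 with DESeq2's Wald test (21.8% false calls in the simulation), and 1379 and 715 with limma-voom and library weights. There were 96 higher genes with limma-voom, 59 higher with limma-trend on FPKM, and 49 lower where a log2 fold change of at least 1 was also asked, which removes genes by construction. Leaving out 1 library gave 4 to 1837 higher and 8 to 1392 lower genes, the extremes without sham replicate 3 and without TAC replicate 1. These fits have fewer samples, and the cause was not tested further. Other normalizations, filters and limma-trend on log2 CPM stayed within 1.5 times. None of the 227 called genes tested in an alternative changed sign, which says little because none overlapped between the groups.

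Replicate numbers are shared between the groups, but same-numbered libraries did not deviate together (correlations of 0.01, -0.11 and -0.02 for numbers 1, 2 and 3). With 3 libraries per group this cannot exclude pairing, which the titles do not state. The libraries were treated as unpaired in the main test. With the replicate block, 48 genes were higher and 26 lower, 61 of them among the 227, and 19 lists were called. The added list was that of mesothelial, Schwann cell and mast cell markers, lower (adjusted p = 0.0412).

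Of 28 gene lists, 18 were called with the preset correlation, 0 with an estimated correlation and 4 with fry, and 17 to 20 when 1 library was left out. The 4 were the chemokine, cytosolic DNA sensing, T and NK cell, and red blood cell and platelet lists (adjusted p = 0.0484 each). Trex1 and Gper1 stayed negative and uncalled in every alternative that tested them. The fit without fractional counts left out Trex1, and the minimum count of 100 left out Gper1. Their log2 fold changes ran from -0.38 to -0.04 and from -0.47 to -0.11, with adjusted p from 0.130 to 0.894 and from 0.214 to 0.842.

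Signs reversed in 7 named genes, all uncalled. The log2 fold change of mt-Co3 was 0.0076 with a minimum count of 100. That of Pkm was -0.014 with DESeq2 size factors, -0.017 with upper-quartile factors, -0.014 with DESeq2's Wald test, -0.013 without a filter, -0.034 with library weights, -0.011 on FPKM and -0.015 without mitochondrial genes. With 1 library left out, the ranges were -0.069 to 0.40 for Lpl, -0.14 to 0.044 for mt-Co3, -0.087 to 0.064 for Pkm and -0.21 to 0.30 for Dusp1. They were -0.45 to 0.021 for Dcn, -0.057 to 0.31 for Rgs5 and -0.71 to 0.20 for Scd1. The cause was not tested. Depth limits genes of a few CPM such as Gper1, and 3 libraries per group recovered 43% of simulated 2-fold changes.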

Other observations

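Lymphocyte, atrial, fat and other marker lists also differed between the hearts. Of 15 B and plasma cell markers none passed and 9 were higher adjusted over the list alone (median log2 fold change 1.19, camera adjusted p = 0.00181, adjusted p = 0.460 with an estimated correlation). A single library held the largest values. Igkc, the immunoglobulin kappa constant gene, was at 3855 CPM in TAC replicate 2 against 38.4 and 71.9 CPM in TAC replicates 1 and 3 and 11.6 to 21.0 CPM in sham. Jchain was at 1037 CPM there against at most 18.8 CPM elsewhere. Among 12 T and NK cell markers none passed. Lck, Cd3g, Il7r, Cd8a and Cd8b1 were higher adjusted over the list alone (median 0.86, camera adjusted p = 0.00833, adjusted p = 0.386 with an estimated correlation and 0.0484 with fry). Cd28 and Cd4 were at -0.35 (SE 0.25) and 0.87 (SE 0.35). Atrial and conduction markers were shifted down, with 0 of 16 passing and 7 lower adjusted over the list alone (median -0.59, camera adjusted p = 0.00134, adjusted p = 0.460 with an estimated correlation). Its most abundant member, Nppa, went the other way at 0.38 (SE 0.21), and Myl4, the atrial light chain gene, was at -0.49 (SE 0.22). Adipocyte markers had a median of -0.69 (camera adjusted p = 9.34e-04, adjusted p = 0.515 with an estimated correlation), with 0 of 16 passing and Aqp7 lower adjusted over the list alone. The call was lost without TAC replicate 3 (adjusted p = 0.269), in which the list median was -2.78 against -0.31 and -0.13 in TAC replicates 2 and 1. Scd1 and Pnpla2 were at -0.27 (SE 0.62) and -0.60 (SE 0.25).

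Clock, senescence and mixed marker lists were not called. Nr1d1, a repressor of the circadian clock, fell from 149 ± 31.3 CPM in sham to 57.8 ± 10.2 CPM in TAC (SD, n = 3 each; log2 fold change -1.36, SE 0.19, edgeR adjusted p = 0.0229). Its counts were fractional, so some of its reads were divided between genes. Nr1d1 overlaps Thra, whose counts were also fractional and which was also lower (log2 fold change -0.67, SE 0.11, edgeR adjusted p = 0.0327). Nr1d1 was the only one of 18 clock genes to pass, and Nfil3 was the only higher one adjusted over the list alone (median -0.05, camera adjusted p = 0.548). Mmp3, a matrix metalloproteinase, was the only one of 19 senescence genes to pass (log2 fold change 2.198, SE 0.34, adjusted p = 0.0279), joined by Mmp12 adjusted over the list alone (median 0.11, camera adjusted p = 0.352). Mesothelial, Schwann cell and mast cell markers had 0 of 16 passing over all genes or adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.106). Of the fits without 1 library, they were called lower without sham replicate 1 (adjusted p = 8.63e-04) and without TAC replicate 2 (adjusted p = 0.0249). Upk3b and Msln were at -0.94 (SE 0.45) and -0.74 (SE 0.57).

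All tests below were chosen after the result was seen, except the count of splits. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 227 genes and the highest of the other 9 called 0 with edgeR, with up to 1365 genes at an unadjusted p under 0.05, and 1 of the 10 splits, the real one, gave as many genes. Each of the other 9 has sham and TAC libraries on both sides. Any group difference then adds to the spread within a side, so few calls were likely there beforehand and the comparison decides nothing.

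TAC replicate 1 lay between the sham and the other TAC libraries. On genes chosen from 2 sham libraries and TAC replicates 2 and 3 alone, where 0 is the sham and 1 the TAC level, its median position was 0.41, 0.37 and 0.35 as sham replicate 1, 2 or 3 was held out. That of the held-out sham library was 0.12, 0.00 and 0.01. Choosing genes on TAC replicates 2 and 3 can by itself place another TAC library below 1. No other TAC library was placed for comparison. The smallest gap, 0.281, argues against a sham library under a TAC label, and its total of 25799573 counts, above the median of the 6 libraries, against low depth. Sham RNA would need a share of 0.721 of the library, which the choice of genes may overstate. Mixing at that share would leave each gene at 0.721 of its sham level or more. However, 7 of 186 genes called lower without the library were under 0.361 times their lowest sham level, Pttg1 at 0.0647, which argues against such mixing as the source. Mixing at a much smaller share, or with RNA unlike these 3 sham libraries, and a smaller response to the surgery in that heart stay open and were not tested.

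Higher neutrophil genes in TAC may come from blood left in the tissue, from infiltrating cells, or from both. The ratio of the larger to the smaller mean total of the groups, 1.04, argues against depth. Blood of constant make-up would raise neutrophil and haemoglobin genes alike. The neutrophil median exceeded that of 4 haemoglobin genes (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt) by 2.27 and 2.25 on the log2 scale in TAC replicates 2 and 3, by -0.22 in TAC replicate 1 and by -0.76 to 0.50 in sham, a TAC mean of 1.44 ± 1.43 (SD, n = 3). Residual blood thus stays open for TAC replicate 1, and blood with more neutrophils per red cell stays open for all 3.

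Several called genes were all-or-none between the groups, which prompted the hypothesis of a strain or substrain difference between sham and TAC animals. Called genes with another called gene of a different name family within 1 Mb numbered 66 of 227, the median of 10000 random lists matched on expression (permutation p = 0.519). This count gave no sign of it, although a few loci among 227 genes would not raise it. A window of 1 Mb also cannot join Pttg1, Cyfip2 and Olfr1396, whose starts on chromosome 11 lie further apart. None of them was among the 66, so the hypothesis of a strain or substrain difference stays open. With no excess of neighbours to explain, the share of the 66 with fractional counts (24.2%) and the position of TAC replicate 1 in them against the other 161 (permutation p = 0.372) decide nothing about shared reads or a graded response. For Tpm3-rs7, up as Tpm3 fell from 92.5 to 27.4 CPM, the summed count of both changed by 0.15 on the log2 scale (95% interval -0.57 to 0.88). Reads moved between the pair would leave the sum unchanged. A separate gain of Tpm3-rs7 and loss of Tpm3 of like size would do the same, so the sum cannot tell them apart. A sequence difference in Tpm3 between the animals is a candidate source of moved reads and was not tested.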
